A study of Mus musculus with 30 samples.

How the data were processed

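RNA from mouse cortex was measured on 30 Affymetrix microarrays, 6 from E14.5 neocortex and 24 from P0.5 frontal, parietal and occipital brain tissue. The values used here are the log2 probe set signals as deposited by the authors, whose labels name Affymetrix Expression Console 1.1 and RMA (background correction, normalization across arrays and summary per probe set), without saying which tool did which step or the version of RMA. The values were left on this scale and were not normalised again. The 2 stages came in separate tables. The label protocol names the Gene 1.0 ST array for all samples, but the probe set names of the E14.5 table are those of an older array type with probes near the 3' end, so the stages were fitted apart and their signal levels were not compared. Signals ranged from 2.86 to 14.0 at E14.5 and from 1.77 to 14.6 at P0.5, and the array medians lay within 5.12 to 5.15 and within 7.42 to 7.52. Arrays give no count depth, and their number limits the precision.

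The E14.5 table held 45101 probe sets, of which 34958 named exactly 1 gene, 932 several genes and 9211 none. The P0.5 table held 35557, of which 21789 named 1 gene, 1621 several and 12147 none. Probe sets naming several genes or none were left out. For each gene the probe set with the highest mean over the arrays of its table was used, which gave 18194 genes at E14.5 and 19938 at P0.5, with 16553 in both. No filter on dim genes was applied. Gene symbols were looked up in a mouse reference annotation, and 0 had to be updated. The annotation served only for names and for the order of genes along the chromosome. The build behind the arrays is not named in the files, so no coordinates are given. All data columns were assigned to a sample from the labels.

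Groups were genotype at E14.5 (3 arrays each) and genotype by region at P0.5 (4 arrays each). Differences were fitted with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend), two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of its comparison. The regional comparisons at P0.5 came from 1 fit of the 24 arrays with 6 groups, and the interaction contrast in it tested whether the frontal minus occipital difference was the same in KO and WT. For KO against WT over the regions, the 3 same-numbered arrays of a genotype were averaged first, which gave 4 KO and 4 WT values, since the labels do not say whether they came from 1 animal.

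The 26 gene lists (293 genes, of which 278 were measured at E14.5 and 277 at P0.5), the comparisons, the rule for named genes and the main alternatives were fixed before the data were examined. The lists held markers of cortical neuron types, progenitors, glia, other tissues, cortical areas, axon guidance, adhesion and receptors. Some genes stand in more than 1 list. Each list was tested with camera from limma, with a preset correlation of 0.01 between genes, with a correlation estimated from the data, and with fry. The p were adjusted over the lists of a comparison, and members were also adjusted over the list alone. The genes named are Tbr1, the 10 largest rises and falls for KO against WT over regions and for WT frontal against occipital tissue, the 5 largest each way in the other P0.5 comparisons, and up to 4 members of each list by p. The rises and falls were taken from called genes whose replicate values did not overlap between the groups, with no overlap rule for the interaction.

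Whether same-numbered arrays were paired was checked by correlating their residuals over genes. At E14.5 each of the 3 KO arrays correlated best with the WT array of its own number (0.125 to 0.445), so values with the number as a block stand beside the E14.5 result. At P0.5 all 4 same-numbered pairs of WT parietal with WT occipital arrays lay over 0.1 (from 0.124 to 0.276, and 3 best with their own number), and the calls with and without the block are given for these. Over the 10 pairs of groups checked at both stages, 13 of 39 arrays correlated best with their own number. WT replicate 2 had a Y-linked mean of 5.76 in parietal and 9.44 in occipital tissue, so a pairing by number stays uncertain. In every other pair of groups at P0.5 at least 1 of the 4 same-numbered pairs lay under 0.1 (lowest -0.471, for frontal KO and WT), and these arrays were fitted as sharing only a number. This does not exclude a pairing. For WT frontal with WT occipital arrays all 4 correlations were positive (0.0581 to 0.393), 3 over 0.1 and 1 best with its own number. With the number as a block that comparison gave 1076 calls, against 1202 without it. The alternatives tried were the mean of a gene's probe sets, leaving out the dimmest 30% of genes, subtracting array medians, no intensity trend, a 1.5-fold minimum, array weights, blocks by replicate number, a fit of only the arrays compared, and leaving out each array in turn (over the regions, the 3 arrays of a genotype and number together). Added after the data had been seen were the mean level of the 3 measured Y-linked genes (Eif2s3y, Kdm5d and Uty) as a covariate, leaving out WT frontal replicate 4 and KO parietal replicate 2, for neighbouring regions the fits of only 8 arrays and with a block, the E14.5 list values without KO replicate 1, and second marker lists for meninges and fibroblasts, choroid plexus and thalamus at E14.5. The sex of the animals is not in the labels, and no groups were made from these levels. In 5 P0.5 arrays Xist was intermediate and the Y-linked genes were high, and the labels do not say whether tissue of several animals was pooled, so how many animals an array stands for, and what the Y-linked level means in such an array, stays open.

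The fits were tested on simulated data with known changes. Of genes changed by 0.5 on the log2 scale, 19.4% were called in the E14.5 design, 97.0% over the regions, 76.1% in parietal tissue and 38.8% in the interaction. Of genes changed by 1, 49.3% were called at E14.5 and 98.5% or more in each P0.5 comparison. The simulated noise was drawn independently for each gene and array. It held no outlying array, pairing or difference in Y-linked level, so these shares may not hold for the real arrays.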

Results

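Gene expression in the developing mouse cortex with and without Tbr1 was measured on 30 microarrays. Tbr1 is a T-box transcription factor made by early-born neurons of the cortex, among them layer 6 corticothalamic neurons, subplate neurons and Cajal-Retzius cells. All mice were of the CD1 strain, and were labelled as Tbr1 homozygous null (KO) or wild type (WT). At E14.5 the neocortex of 3 KO and 3 WT samples was measured. At P0.5 frontal, parietal and occipital brain tissue was measured in 4 KO and 4 WT samples each, which made 24 arrays in 6 groups of 4. The deposited values were log2 signals per probe set. The array medians lay between 5.12 and 5.15 at E14.5 and between 7.42 and 7.52 at P0.5, and the number of arrays limits the precision of each comparison. The labels gave neither the sex of the animals nor whether same-numbered arrays of different regions came from 1 animal.

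Tbr1 transcript was lower in KO tissue in all 3 regions at P0.5. Its log2 signal in frontal tissue was 9.73 ± 0.21 in KO and 10.35 ± 0.18 in WT (SD, n = 4 each), in parietal tissue 9.69 ± 0.18 and 10.27 ± 0.15, and in occipital tissue 9.27 ± 0.15 and 10.11 ± 0.29. The log2 differences were -0.62 (SE 0.124, limma adjusted p = 0.00189), -0.58 (adjusted p = 0.00887) and -0.84 (adjusted p = 2.93e-04), which are 1.54-fold, 1.49-fold and 1.79-fold decreases. In each of the 3 regions every KO array lay below every WT array. At E14.5 the signal was 7.83 ± 0.76 in KO and 9.12 ± 0.23 in WT (SD, n = 3 each), a difference of -1.29 (SE 0.368) that did not pass correction over all genes (limma adjusted p = 0.85). KO replicate 1 was at 8.685, close to the lowest WT array (8.895), and KO replicates 2 and 3 were at 7.234 and 7.567. Tbr1 was read by 1 probe set in each table. The files do not say which part of the gene was deleted relative to the probes, so the remaining signal checks the genotype labels only in part.

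**Figure D1:**
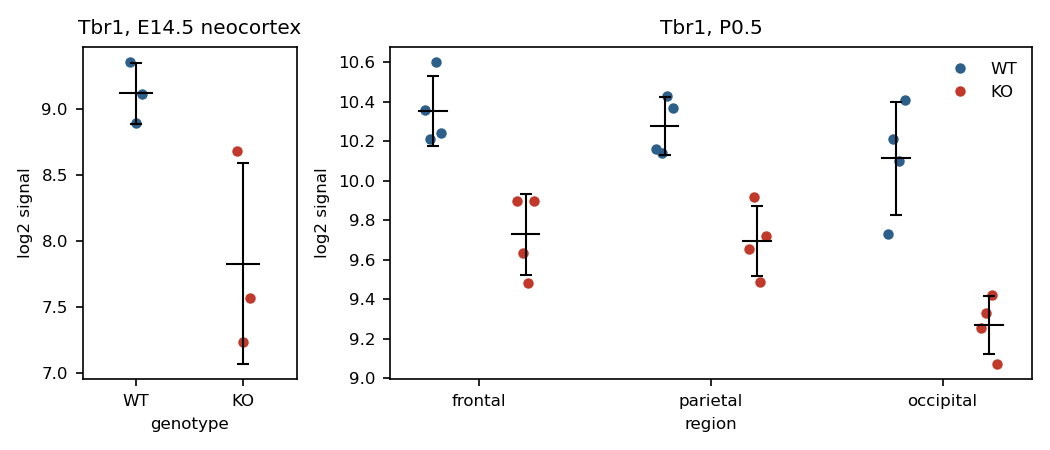
Log2 signal of Tbr1 per array, by genotype at E14.5 (left) and by region and genotype at P0.5 (right); points are arrays, and bars give the mean and SD. The KO arrays lie below the WT arrays of the same stage and region, with group means of 7.83 against 9.12 at E14.5.

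The comparison of KO with WT over the 3 regions asked which genes changed in newborn cortex without Tbr1, whatever the region. With a preset correlation between genes (camera), the lists of layer 6 and of subplate neurons were lower in KO as sets, and those of layer 5 subcerebral neurons and of astrocytes were higher. With an estimated correlation none of the 4 passed (adjusted p = 0.0994 for each of the first 3 and 0.154 for astrocytes). Tle4, a transcriptional corepressor of layer 6 neurons, fell by 1.02 on the log2 scale (SE 0.0704, limma adjusted p = 9.15e-07; 4 KO and 4 WT values, each the mean of 3 regions). Fezf2, the transcription factor that specifies layer 5 subcerebral neurons, rose by 0.69 (SE 0.0515, adjusted p = 1.64e-06), and Nefm, the medium neurofilament chain, rose by 1.36, or 2.57-fold (SE 0.0604, adjusted p = 2.16e-08). In all, 1488 of 19938 genes were called, 939 higher and 549 lower in KO, with a median change of 1.21-fold, and 129 changed at least 1.5-fold. The count was 963 without the 3 arrays of KO replicate 1, 989 without those of KO replicate 4, and 824 when the mean level of the Y-linked genes was a covariate in a fit of the 24 arrays, against 1891 in that fit without the covariate. With it 54 of 75 called genes named by rule stayed called and 74 kept their sign.

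The 10 largest rises over the regions, among called genes whose KO values all lay above the WT values, began with Xist, the noncoding RNA of the inactive X chromosome, which was 3.51 higher on the log2 scale. They went on with Vwc2l, a secreted von Willebrand factor C domain protein (1.57), Nefm, Cwc22, a splicing factor (1.34), Nefl, the light neurofilament chain (1.31), Tuba4a, an alpha-tubulin (1.30), Epha6, an Eph receptor (1.23), Neurod1, a neuronal differentiation factor (1.19), Slc4a10, a bicarbonate transporter (1.13), and Ptprn, a protein of dense-core vesicles (1.08). The 10 largest falls, chosen in the same way, began with the Y-linked genes Eif2s3y (-2.56) and Uty (-1.83). They went on with the metalloprotease Adamts3 (-1.30), the melanocortin receptor Mc4r (-1.29), Arhgap29 (-1.18), the cadherin Cdh9 (-1.12), the heparan sulfate enzymes Hs3st5 (-1.12) and Sulf1 (-1.04), the Kit ligand Kitl (-1.07) and the thioredoxin-binding protein Txnip (-1.05). Their standard errors lay between 0.0458 and 0.469, and their limma adjusted p between 1.21e-08 (Slc4a10) and 5.63e-04 (Uty). The mean level of the 3 measured Y-linked genes was 5.39, 7.23 and 8.35 in KO frontal, parietal and occipital tissue and 9.04, 8.31 and 9.32 in WT, beside all differences between KO and WT in these regions. Without WT frontal replicate 4 and KO parietal replicate 2 together, Cwc22 was no longer called. Xist, fitted with the Y-linked level as a covariate, stood at 1.04 (limma adjusted p = 0.175), Eif2s3y at -0.20 (0.129) and Uty at 0.079 (0.66).

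Of the lists fixed before the data were examined, those of layer 6 and subplate neurons fell as sets and that of layer 5 subcerebral neurons rose over the regions with the preset correlation, though not with an estimated one. Of 11 measured genes of layer 6 corticothalamic neurons, 7 fell, 1 rose and 3 were not called (adjusted over the list alone, 8 fell and 2 rose). The 4 with the smallest p were Tle4, the synaptotagmin Syt6 (-0.58), Tbr1 (-0.68) and the heparan sulfate sulfotransferase Hs3st4 (-0.49). Tbr1, null in KO by design, counts among the falls of this list here and in each region. No count or set test was made without it. The set test with a preset correlation (camera) gave an adjusted p of 5.60e-06, and adjusted p = 0.0994 with an estimated correlation. Of 10 genes of subplate and layer 6b neurons, 5 fell and 5 were not called, with Nxph4 (-0.49) and Ccn2 (-0.35) among those that fell (7 fell adjusted over the list alone; adjusted p = 1.21e-04, and 0.0994 with an estimated correlation). The 5 subplate calls were 2 without KO replicate 1, 3 without WT replicate 4 and 2 with the Y-linked level as a covariate. Ccn2 then stood at -0.29 (SE 0.0864, against 0.0666 in the same fit of 24 arrays without it, limma adjusted p = 0.0575). Of 12 genes of layer 5 subcerebral neurons, 7 rose, 1 fell and 4 were not called, with Crim1 (0.56), Etv1 (0.57) and Crym (0.47) rising beside Fezf2 (7 rose and 2 fell adjusted over the list alone; adjusted p = 4.74e-05, and 0.0994 with an estimated correlation). Of 9 genes of Cajal-Retzius cells, 4 fell and 5 were not called, led by Reln, the secreted protein that guides cortical layering (-0.53), Nhlh2 (-0.49) and Trp73 (-0.25) (5 fell adjusted over the list alone; adjusted p = 4.74e-05, and 0.0994 with an estimated correlation). Of 12 genes of upper layer and callosal neurons, 1 fell (Rorb, -0.74) and 11 were not called, and the set test gave an adjusted p of 0.921.

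**Figure D2:**
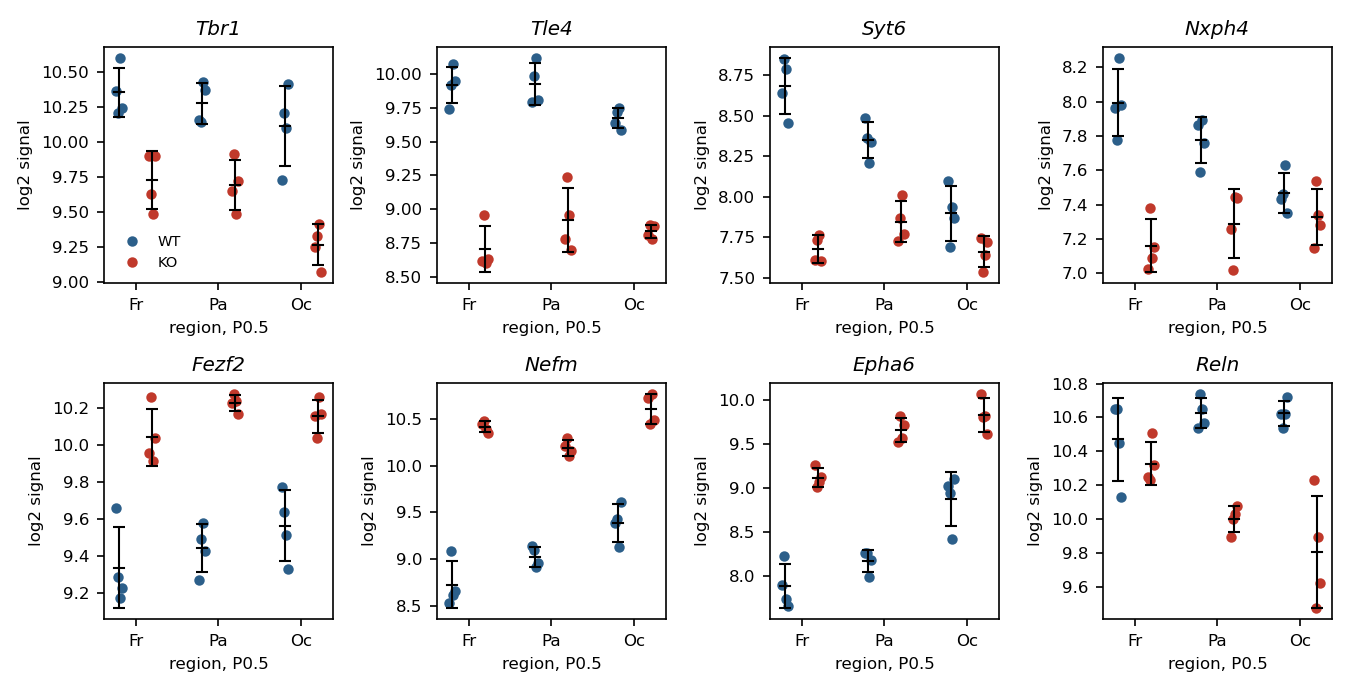
Log2 signal per P0.5 array of Tbr1 and 7 genes of the lists or of the largest changes, by region (Fr frontal, Pa parietal, Oc occipital) and genotype; points are arrays, and bars give the mean and SD of 4 arrays. Tle4 lies lower and Nefm, Fezf2 and Epha6 lie higher in KO in each region, whereas the difference of Nxph4 is largest in frontal tissue (-0.83) and that of Reln in occipital tissue (-0.82).

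The lists of astrocytes, radial glia, microglia and oligodendrocyte lineage were also higher in KO over the regions as sets with the preset correlation, and none of them passed with an estimated correlation. Of 7 astrocyte genes, 4 rose and 3 were not called, among them the water channel Aqp4 (0.65), the folate enzyme Aldh1l1 (0.54), the glutamate transporter Slc1a2 (0.39) and the glial filament Gfap (0.56) (5 rose adjusted over the list alone; camera adjusted p = 1.21e-04, and adjusted p = 0.154 with an estimated correlation). Of 11 radial glia genes, 6 rose and 5 were not called, led by Pax6 (0.34) and Hes1 (0.32) (7 rose adjusted over the list alone; adjusted p = 3.73e-05, and 0.178 with an estimated correlation). Of 9 microglia genes, 3 rose and 6 were not called, and the 3 were the complement genes C1qb (0.47), C1qa (0.29) and C1qc (0.53), none of them called without KO replicate 1, and C1qc in 5 other cases of 1 replicate left out (highest adjusted p 0.0572, 0.0724 and 0.131; 5 rose adjusted over the list alone; adjusted p = 1.89e-04, and 0.26 with an estimated correlation). Of 7 oligodendrocyte lineage genes, the myelin genes Cnp (0.29) and Mbp (0.22) rose and 5 were not called, and the set test gave an adjusted p of 0.0326, or 0.324 with an estimated correlation. Of 7 blood vessel genes, the VEGF receptor Kdr fell (-0.66) and 6 were not called (3 fell adjusted over the list alone; adjusted p = 0.00143, and 0.451 with an estimated correlation). The 14 cell division genes (0 called, camera adjusted p = 0.0113) and the 7 choroid plexus genes (0 called, adjusted p = 0.0483) fell as sets with the preset correlation, with adjusted p = 0.632 for each with an estimated correlation. The 6 radial glia calls were 2 without KO replicate 1, 2 without KO replicate 4, 3 without WT replicate 4 and 0 with the Y-linked level as a covariate. With the covariate Pax6 stood at 0.32 (SE 0.122, against 0.0923 in the same fit of 24 arrays without it, limma adjusted p = 0.185) and Hes1 at 0.29 (SE 0.0877 against 0.0664, adjusted p = 0.0605). C1qb stood at 0.41 (SE 0.145 against 0.111, adjusted p = 0.136), C1qa at 0.29 (0.091 against 0.0686, adjusted p = 0.0706) and C1qc at 0.49 (0.171 against 0.129, adjusted p = 0.13). Kdr stood at -0.62 (SE 0.202 against 0.153, adjusted p = 0.0913). These genes kept their direction and most of their size, with a wider error, as did the radial glia gene Slc1a3 (0.40, SE 0.133 against 0.1, adjusted p = 0.105). Sox2, also of that list, went from 0.22 to 0.10 (SE 0.12 against 0.0948, adjusted p = 0.833), and it was not called in the fit of 24 arrays without the covariate (adjusted p = 0.17).

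Genes of cortical area identity, axon guidance and adhesion changed both ways over the regions. Of 8 caudal cortex genes, 5 rose, 1 fell and 2 were not called, with the teneurin Tenm3 (0.41) and Tshz2 (0.61) among the risers and Nr2f2 (-0.36) falling, though not without KO replicate 2 or 4 (highest adjusted p 0.0704; 5 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.00561, and adjusted p = 0.0994 with an estimated correlation). Of 10 rostral cortex genes, Epha7 (0.53), Cdh8 (0.41) and Spry2 (0.34) rose, 2 fell, with Auts2 (-0.29) among them, and the set test gave an adjusted p of 0.498. Of 38 axon guidance genes, 6 rose, 4 fell and 28 were not called (adjusted p = 0.211), and Epha6, Slit2 (0.67), Epha5 (0.38) and Epha7 rose. Of 22 cadherins and protocadherins, 6 rose, 5 fell and 11 were not called (adjusted p = 0.35). Cdh9 fell, and Pcdh19 (0.45), Cdh7 (0.59) and Pcdh8 (0.44) rose. Of 20 glutamate receptor genes, 3 rose and 4 fell (adjusted p = 0.498), with the NMDA receptor subunit Grin3a (0.92) rising and Grm3 (-0.37) falling. Of 10 striatum genes, 3 fell and 2 rose (adjusted p = 0.593), among them the dopamine receptor Drd1 (-0.91) and the opioid precursor Penk (0.46). No set test passed for GABAergic interneurons (adjusted p = 0.0904), intermediate progenitors (0.429), olfactory bulb (0.878), hippocampus (0.128), thalamus (0.664), meninges and fibroblasts (0.429), red blood cells (0.84) or immediate early and stress genes (0.484). Of these, the somatostatin gene Sst (0.38), the thalamus gene Prkcd (0.29) and Jun (0.30) rose. Tshz2 stood at 0.57 with the Y-linked level as a covariate (SE 0.17, against 0.129 in the same fit of 24 arrays without it, limma adjusted p = 0.0613) and Nr2f2 at -0.38 (0.13 against 0.0979, adjusted p = 0.121). Sst stood at 0.27 (SE 0.137 against 0.106, adjusted p = 0.41) and Jun at 0.27 (0.0784 against 0.0596, adjusted p = 0.0557). The 5 caudal rises were 3 without KO replicates 1 or 4 or WT replicates 2 or 4 and 2 with the covariate. Calls lower in KO were 2 for axon guidance without KO replicates 2 or 4 or WT replicates 1 or 3. They were 2 for glutamate receptors without KO replicate 1 or WT replicates 2 or 3, and 1 for rostral cortex without KO replicate 4 or WT replicate 4. Calls higher in KO were 5 for glutamate receptors without WT replicate 2 and 1 with the covariate. They were 1 for striatum without KO replicates 1, 2 or 3 or WT replicate 2. In each comparison where a list passed the set test with the preset correlation, its median, mean and set test pointed 1 way. They pointed both ways over the regions in the rostral cortex, striatum and thalamus lists.

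**Figure D3:**
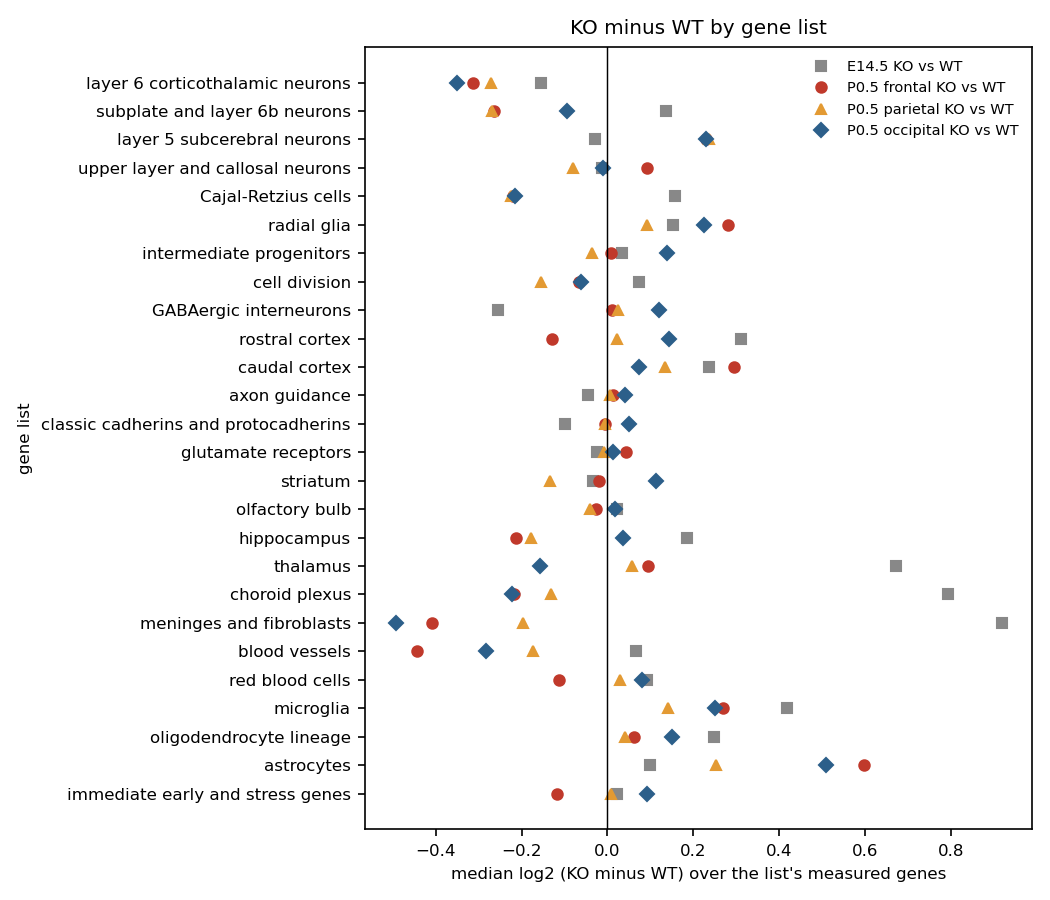
Median log2 difference (KO minus WT) over the measured genes of each of 26 gene lists, for E14.5 neocortex (squares) and P0.5 frontal (circles), parietal (triangles) and occipital (diamonds) tissue. Layer 6 genes lie below 0 in all 4 comparisons, and meninges and fibroblast genes lie at 0.92 at E14.5 and at -0.41, -0.20 and -0.49 in the P0.5 regions.

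In frontal tissue alone, the comparison asked what changed at the rostral end of the newborn cortex. Tle4 fell by 1.22 on the log2 scale (SE 0.1, limma adjusted p = 1.13e-08, n = 4 and 4), Syt6 fell by 1.0, and the SoxD factor Sox5 fell by 0.88. Of the 11 layer 6 genes 5 fell and 1 rose (6 and 2 adjusted over the list alone), and of the 10 subplate genes 4 fell (5 adjusted over the list alone), with Nxph4 at -0.83 and Ccn2 at -0.64. Each of these lists had a camera adjusted p of 0.00165, and adjusted p = 0.0572 with an estimated correlation. Of the 12 layer 5 genes 4 rose and 2 fell (camera adjusted p = 0.0193, and adjusted p = 0.281 with an estimated correlation). Among them Fezf2 rose by 0.70 (SE 0.0995, adjusted p = 3.44e-05) and the contactin Cntn6 by 1.18. Nefm rose by 1.70, which is 3.24-fold, and Vwc2l by 2.22, which is 4.65-fold. The Y-linked genes were lower in KO frontal arrays, with a mean level of 5.39 ± 0.41 in KO and 9.04 ± 0.07 in WT (SD, n = 4 each), and Xist was at 12.0 to 12.2 in KO and at 5.65 to 6.39 in WT, beside all of these differences. In the other groups these levels were mixed, with a Y-linked mean of 8.35 in KO and 9.32 in WT occipital tissue and of 7.23 in KO and 8.31 in WT parietal tissue.

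The 5 largest frontal rises were Xist (6.01), Vwc2l, Cwc22 (1.94), Neurod1 (1.73) and Nefm, and the 5 largest falls were Eif2s3y (-4.98), Uty (-3.50), Kdm5d (-2.45), Mc4r (-2.0) and Kitl (-1.70). The call of Cwc22 was lost without KO replicate 3, WT replicate 2 or WT replicate 4 (highest limma adjusted p 0.0779). Of 8 caudal cortex genes 1 rose, Tenm3 by 0.89, and 5 rose adjusted over the list alone (camera adjusted p = 0.00852, and 0.0572 with an estimated correlation). Of 7 astrocyte genes 4 rose, with Aldh1l1 at 0.81 (adjusted p = 0.0119, and 0.263 with an estimated correlation). These 4 were 1 without KO replicate 1 or 4 and 2 without KO replicate 3 or WT replicate 4. With the Y-linked level as a covariate 1 was called, and Gfap stood at 0.91, Aqp4 at 0.58 and Slc1a2 at 0.45. Of the other counts above, the layer 6 rise was lost without KO replicates 1 or 4 or WT replicates 3 or 4. The 2 layer 5 falls were 0 without KO replicate 1 and 1 without KO replicate 3 or WT replicate 3. Caudal rises were 2 without KO replicate 2 and 3 without WT replicate 3. With the covariate 1 of the 4 subplate falls was called. Outside these lists Drd1 (-1.08), Cdh9 (-1.34) and Grin3a (1.13) changed. Of 26 lists the camera test called 9, with radial glia (adjusted p = 0.0162) and microglia (0.0047) higher and Cajal-Retzius (0.0388) and blood vessel genes (0.0119) lower beside those named. With an estimated correlation it called none, and these last 4 had adjusted p of 0.436, 0.354, 0.411 and 0.556. In all, 1499 genes were called in frontal tissue, 938 higher and 561 lower, with a median change of 1.31-fold. The count was 788 without KO replicate 1, 749 without KO replicate 4, 944 without WT replicate 3, 876 without WT replicate 4 and 2454 without WT replicate 1. It was 247 with the Y-linked level as a covariate, 687 in a fit of the 8 frontal arrays alone, 2606 with array weights and 284 with a 1.5-fold minimum. With the covariate 27 of 58 called genes named by rule stayed called and 56 kept their sign. Of those given above, Ccn2 stood at -0.53 (SE 0.157, against 0.115 before, limma adjusted p = 0.12) and Cwc22 at 2.10 (0.721, 0.521 before, adjusted p = 0.208). Xist went to 1.27 (adjusted p = 0.591), Eif2s3y to -0.45 (0.0842), Uty to 0.17 (0.644) and Kdm5d to 0.28 (0.461).

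In parietal tissue the same comparison found layer 6 genes lower and layer 5 genes higher in KO. Of the layer 6 genes 5 fell and 1 rose, with Tle4 at -1.01 (SE 0.1, limma adjusted p = 9.27e-07, n = 4 and 4) and Thsd7b at 0.61, and of the layer 5 genes 4 rose and none fell, led by Fezf2 (0.79) and Etv1 (0.76). Layer 6 (camera adjusted p = 1.36e-04, 0.0257 with an estimated correlation), subplate (8.86e-04 and 0.0391), layer 5 (1.16e-06 and 0.0175) and caudal cortex lists (0.00461 and 0.0257) passed both set tests. Cajal-Retzius (0.00221 and 0.167) and cell division genes (0.00461 and 0.662) were lower and astrocyte genes (0.0199 and 0.238) higher with the preset correlation alone. Of the 10 subplate genes 1 fell (0 without KO replicate 2 or WT replicates 1 or 3), and 5 fell adjusted over the list alone. The 5 largest rises were Vwc2l (1.70), Epha6 (1.49), Neurod1 (1.45), Slc4a10 (1.27, 2.42-fold) and Nefl (1.25), and the 5 largest falls were Cdh9 (-1.47), Kitl (-1.31), the transcriptional repressor Bcl6 (-1.21), Mctp1 (-1.16) and Arhgap29 (-1.13). Reln fell by 0.62 (adjusted p = 0.0027). In all, 361 genes were called, 212 higher and 149 lower, with a median change of 1.42-fold. The count was 237 without KO replicate 4, 122 with a 1.5-fold minimum and 1241 with array weights.

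In occipital tissue the fall of layer 6 genes was accompanied by a fall of the Cajal-Retzius genes Reln (-0.82, SE 0.118, limma adjusted p = 2.26e-04, n = 4 and 4) and Ndnf (-1.38). Of the layer 6 genes 3 fell, Tle4 (-0.83), Tbr1 and the forkhead factor Foxp2 (-0.80), and 5 fell without WT replicate 1 and 8 adjusted over the list alone (camera adjusted p = 5.86e-11, 6.38e-04 with an estimated correlation). Of the layer 5 genes 4 rose, Fezf2 (0.59), Crim1 (0.68), Crym (0.64) and the annexin-binding protein S100a10 (0.69) (camera adjusted p = 0.0046, and adjusted p = 0.128 with an estimated correlation). Of the 10 subplate genes none was called (adjusted p = 0.334), and Nr4a2 stood at -0.57 (adjusted p = 0.336). The 5 largest rises were Tuba4a (1.26), Nefm (1.22), Nefl (1.15), the growth factor Fgf9 (1.02) and Slc4a10 (1.00), and the 5 largest falls were Adamts3 (-1.44), Ndnf, Arhgap29 (-1.31), Mctp1 (-1.23) and Hs3st5 (-1.18). In all, 267 genes were called, 152 higher and 115 lower, with a median change of 1.43-fold, or 120 and 118 of 238 when each array's median was subtracted, and 163 and 195 of 358 without WT replicate 1. The camera test called 10 lists, and with an estimated correlation the list of layer 6 alone. Beside layer 6 and layer 5 these were radial glia (adjusted p = 4.14e-04, 0.183 with an estimated correlation), astrocytes (4.14e-04 and 0.1), oligodendrocyte lineage (0.00215 and 0.128), microglia (0.0135 and 0.464) and rostral cortex (0.0135 and 0.195), all higher. Lower were Cajal-Retzius (7.89e-04 and 0.128), choroid plexus (0.027 and 0.54) and blood vessel genes (0.0282 and 0.616). The count was 155 without KO replicate 3, 122 without WT replicate 2, 127 without WT replicate 3, 89 with a 1.5-fold minimum, 664 with array weights and 419 without WT frontal replicate 4 and KO parietal replicate 2.

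The genes called in the 3 regions overlapped. Of the genes called higher, 166 were shared by frontal and parietal tissue (9.97 by chance), 83 by frontal and occipital tissue (7.15) and 73 by parietal and occipital tissue (1.62). Of those called lower, 113 (4.19 by chance), 66 (3.24) and 48 (0.859) were shared. The 3 comparisons took each gene's spread from the same fit of 24 arrays, so genes of small spread tend to be called together. The counts by chance do not allow for this. In all 3 regions 58 genes were higher and 45 lower, and 1 gene was called in opposite directions in a pair of regions. This was Lmo4, a LIM domain protein, at -0.58 in frontal and 0.49 in parietal tissue, and its parietal call was lost without any of 7 of the 8 arrays (highest adjusted p 0.185). Its values were, with the Y-linked level as a covariate, -0.61 (SE 0.177, against 0.128 before, adjusted p = 0.102) and 0.47 (0.135, 0.128 before, adjusted p = 0.0883). The difference between these regions was not tested. Same-numbered arrays of different regions differed in Y-linked mean for KO replicates 1, 2, 3 and 4 and WT replicate 2 (5.09 in frontal and 9.32 in occipital tissue for KO replicate 1), so they did not all come from the same animals. For WT replicates 1, 3 and 4 the Y-linked levels do not tell, and those overlaps may not be of independent samples. Xist of WT replicate 3 was at 8.65 in parietal tissue, against 6.39 in frontal and 6.24 in occipital tissue.

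The comparison of frontal with occipital tissue in WT asked which genes differed between the ends of the rostrocaudal axis in the newborn brain tissue taken. Caudal cortex genes were higher in occipital tissue. The teneurin Tenm3 had a log2 signal of 9.93 ± 0.23 in frontal and 11.48 ± 0.19 in occipital tissue (SD, n = 4 each), a difference of -1.55 (SE 0.107, limma adjusted p = 8.11e-10), and the nuclear receptor Nr2f1 differed by -1.24 (adjusted p = 6.62e-09). Of 8 caudal cortex genes 4 were higher in occipital tissue and none in frontal tissue, with Fgfr3 (-0.52) and Tshz2 (-1.35) beside these (camera adjusted p = 2.40e-06, 7.83e-04 with an estimated correlation). Of 10 rostral cortex genes, the ETS factor Etv5 was higher in frontal tissue (0.59) and 9 were not called (adjusted p = 0.51). Radial glia genes (3 of 11 lower in frontal tissue, with Fabp7 at -0.70) and axon guidance genes (9 lower and 3 higher of 38, with Epha5 at -0.64, Epha6 at -0.99 and Slit2 at -1.04) had a camera adjusted p of 0.0187 each, and adjusted p = 0.781 with an estimated correlation. The 3 radial glia calls were 1 without WT frontal replicates 2, 3 or 4 or WT occipital replicates 2 or 3, as Pax6 and Sox2 lost their calls (highest limma adjusted p 0.0958 and 0.143). The 3 axon guidance calls higher in frontal tissue were 1 without WT frontal replicate 3 and 0 without WT occipital replicate 2. The choroid plexus gene Ttr was higher in occipital tissue (-3.17, SE 0.881, limma adjusted p = 0.0336). Ppp1r1b (1.03, adjusted p = 9.90e-07) and Drd1 (0.39, adjusted p = 0.0379), of the striatum list, were higher in frontal tissue. Both were also lower in KO than in WT over the regions (-0.39 and -0.91), and which cells gave their signal was not tested. Neither the choroid plexus nor the striatum list passed the set test, and whether other tissue in the samples added to the calls was not tested.

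The 10 genes most above in WT frontal tissue were S100a10 (1.48), Bcl6 (1.39), neuropeptide Y gene Npy (1.33), Mc4r (1.28), the repressor Bhlhe40 (1.26), Klhl29 (1.18), Lrrc9 (1.17), the homeobox gene Mkx (1.15), the TGF-beta receptor Tgfbr1 (1.13) and Lratd1 (1.07). The 10 most above in occipital tissue were the neurotensin gene Nts (-2.51), the nuclear receptor Nr4a2 (-2.08), Egfem1 (-2.08), the growth factor receptor Met (-1.87), Tenm3, Usp17ld (-1.49), the potassium channel subunit Kcng3 (-1.47), Tshz2, the relaxin receptor Rxfp1 (-1.34) and Pla2g7 (-1.33). Of these 20 genes, 1 lost its call when a single array was left out, Usp17ld without any of 6 of the 8 arrays (highest limma adjusted p 0.117), and Nts lost its call in a fit of the 8 arrays alone. In all, 1202 genes were called, 451 higher in frontal and 751 in occipital tissue, with a median difference of 1.30-fold. Between neighbouring regions of WT, 34 genes were called for frontal and parietal tissue and 90 for parietal and occipital tissue. The count of 1202 was 1917 without WT frontal replicate 1, 766 without WT frontal replicate 3, 545 without WT frontal replicate 4, 441 without WT occipital replicate 2 and 556 without WT occipital replicate 3. It was 287 in a fit of the 8 arrays alone, 209 with a 1.5-fold minimum and 782 without WT frontal replicate 4 and KO parietal replicate 2.

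The same comparison in KO asked how the ends of the axis differed without Tbr1. Caudal cortex genes were again higher in occipital tissue, 5 of 8 with 1 the other way (camera adjusted p = 1.23e-04, 0.0043 with an estimated correlation). Nr2f1 differed by -0.88 (SE 0.0957, limma adjusted p = 2.88e-06, n = 4 and 4), and the ephrin Efna5 was higher in frontal tissue by 1.05. Npy (1.91), the activin subunit Inhba (1.67), the vasopressin receptor Avpr1a (1.13), the glypican Gpc5 (1.13) and Il1rapl2 (1.13) were the 5 genes most above in frontal tissue. Eif2s3y (-4.08), Nts (-3.71, 13.0-fold), the zinc finger gene Trps1 (-1.60), the cerebellin Cbln4 (-1.57) and the neuropilin Nrp2 (-1.50) were the 5 most above in occipital tissue, beside a Y-linked mean of 5.39 in frontal and 8.35 in occipital KO arrays. Of these, Eif2s3y was not called without KO frontal replicate 1 or KO occipital replicates 1, 2 or 4, nor Nrp2 without KO occipital replicate 1 (highest limma adjusted p 0.0614 and 0.0575). Eif2s3y went to -0.40 with the Y-linked level as a covariate (adjusted p = 0.0978). Nrp2 then stood at -1.52 (SE 0.437, against 0.343 before, adjusted p = 0.0978) and Il1rapl2 at 1.03 (0.268, 0.212 before, adjusted p = 0.0569). Tbr1 differed by 0.46 in KO (adjusted p = 0.0369, but 0.149 at the highest with 1 array left out and 0.379 with this covariate, at 0.39) and by 0.24 in WT (adjusted p = 0.21).

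Other lists also separated the ends of the axis in KO. Upper layer and callosal genes were higher in frontal tissue, 4 of 12 with 1 lower (camera adjusted p = 0.00431, 0.255 with an estimated correlation), with Pou3f2 at 1.06 (0.85 with the Y-linked level as a covariate, SE 0.23 against 0.189 before, limma adjusted p = 0.069) and Ptn at 0.46. Higher in occipital tissue were radial glia genes (3 of 11; adjusted p = 0.00164, 0.255 with an estimated correlation), subplate genes (2 of 10, Tmem163 at -0.67 and Nr4a2 at -1.36; 0.00398 and 0.17), axon guidance genes (11 of 38 with 5 the other way; 0.00169 and 0.255), hippocampus genes (0 of 6 called; 0.00722 and 0.17) and intermediate progenitor genes (2 of 8; 0.0477 and 0.376). The 3 radial glia calls were 1 without KO frontal replicate 2, and the 2 intermediate progenitor calls 1 without any of 7 of the 8 arrays. The 11 axon guidance calls were 7 without KO occipital replicate 1. These were 0, 0 and 5 with the Y-linked level as a covariate. Notch1 stood at -0.42 (-0.47 before), Slc1a3 at -0.73 (-0.74), Sox9 at -0.34 (-0.30), Dll1 at -0.35 (-0.35) and Insm1 at -0.47 (-0.41). The 4 upper layer calls were 2 and the 5 axon guidance calls the other way 1. In all, 643 genes were called, 293 higher in frontal and 350 in occipital tissue, or 371 and 262 of 633 when each array's median was subtracted, 289 and 251 without KO frontal replicate 2 and 271 and 256 without KO occipital replicate 1. Between neighbouring regions of KO, 47 genes were called for frontal and parietal tissue and 70 for parietal and occipital tissue. The WT and KO comparisons shared 88 genes higher in frontal tissue (6.63 by chance) and 155 higher in occipital tissue (13.2 by chance). These counts by chance do not allow for the spread of each gene, which both comparisons took from the same fit. The count of 643 was 247 with the Y-linked level as a covariate (23 of 41 called genes named by rule stayed called), 199 with a 1.5-fold minimum, 1549 with array weights and 1025 without WT frontal replicate 4 and KO parietal replicate 2.

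Whether the frontal to occipital difference itself depended on Tbr1 was tested as an interaction. The difference of Tenm3 was -1.55 in WT and -0.56 in KO, a change of 0.98 (SE 0.151, limma adjusted p = 0.00162, n = 4 in each of 4 groups). Egfem1 differed by -2.08 in WT and -0.56 in KO (change 1.52, adjusted p = 1.75e-04), Bcl6 by 1.39 and 0.027 (change -1.36, adjusted p = 0.005) and Bhlhe40 by 1.26 and -0.13 (change -1.39, adjusted p = 2.70e-04). The layer 6 gene Syt6 was higher in frontal than occipital tissue in WT (0.78), and in KO the difference was 0.018, a change of -0.77 (adjusted p = 0.00685). Cntn6 went from -1.10 in WT to 0.56 in KO (change 1.66) and Ndnf from -0.87 to 0.82 (change 1.69).

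Beside these, the 5 largest positive changes included Il1rapl2 (1.70) and Klhl4 (1.61), and the 5 largest negative ones Kitl (-1.49), the zinc finger gene Zfp385b (-1.09) and the metalloprotease Pappa2 (-1.05). Single members of other lists also passed, Inhba (1.28), Sema3a (0.81), Pcdh8 (0.70), Ppp1r1b (-0.81), Tmem163 (-0.65) and Nxph4 (-0.69). The calls of Kitl and Nxph4 were each lost without any of 11 of the 16 arrays (highest limma adjusted p 0.131 and 0.105), that of Klhl4 without any of 10 (0.099), and those of Inhba and Tmem163 without any of 4 (0.0622 and 0.062). In all, 83 genes were called, 47 with a positive and 36 with a negative change, or 55 and 16 of 71 when each array's median was subtracted, 40 and 42 without KO occipital replicate 1 and 72 and 75 without WT frontal replicate 1. Of the 83, 43 were called between the ends of the axis in WT and 40 in KO, 41 had a smaller difference in KO than in WT, and 61 had opposite signs in the 2 genotypes. No list passed the set test (lowest camera adjusted p 0.125, for subplate genes), and these changes too stood beside the Y-linked means of the 4 groups given above. The count of 83 was 29 to 50 without KO frontal replicates 1 (46), 3 (45) or 4 (29), KO occipital replicates 2 (50) or 3 (42), WT frontal replicate 4 (34) or WT occipital replicates 2 (31) or 3 (35), and 152, 147 and 187 without KO frontal replicate 2, WT frontal replicate 1 and WT occipital replicate 1. It was 12 with the Y-linked level as a covariate, where Cntn6, Egfem1, Bhlhe40, Syt6 and Tenm3 stayed called among the 18 called genes named by rule. All 18 kept their sign with it, and those not called included Il1rapl2 at 1.61 (SE 0.337, against 0.3 before), Ndnf at 1.43 (0.311, 0.297 before), Kitl at -1.65 (0.375, 0.338 before) and Bcl6 at -1.22 (0.249, 0.227 before). The count was 46 without WT frontal replicate 4 and KO parietal replicate 2, and 530 with array weights.

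**Figure D4:**
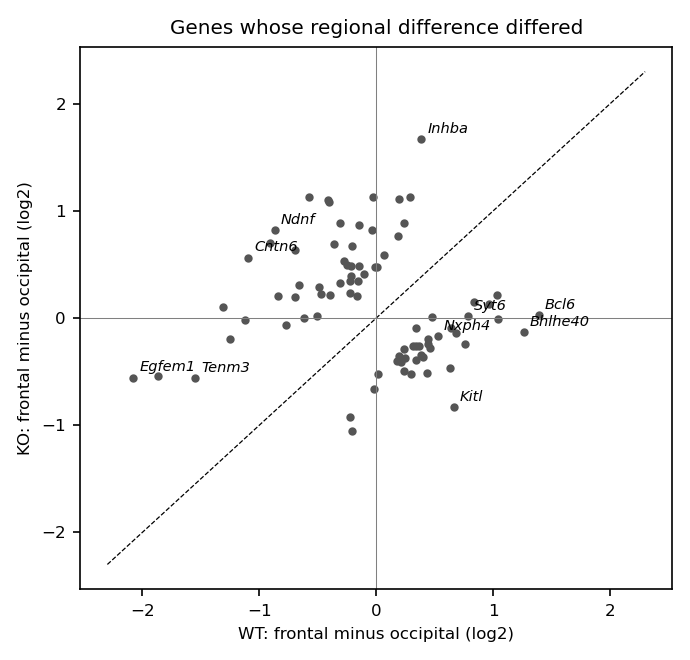
Frontal minus occipital log2 difference in WT (horizontal axis) and KO (vertical axis) of the 83 genes whose difference changed with genotype; each point is a gene, and the dashed line marks equal differences. Egfem1 and Tenm3 have a large difference in WT (-2.08 and -1.55) and a smaller one in KO (-0.56 for each).

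Regional differences were also followed in genes chosen apart from the arrays that measured them. Genes were chosen by the frontal to occipital difference in WT arrays of 2 replicate numbers, 100 each way, and measured in the WT arrays of the other 2 numbers and in KO, over all 6 choices. The frontal genes differed by 0.53 on the log2 scale in the other WT arrays (range 0.42 to 0.64 over the choices) and by 0.32 in KO (0.14 to 0.42). The occipital genes differed by -0.71 in WT (-0.83 to -0.53) and by -0.47 in KO (-0.59 to -0.36). The ratio of the KO to the WT difference was 0.63 on average (range 0.526 to 0.79). The 6 choices share arrays, and no test was run on the ratio. Genes were chosen in WT alone and not in KO, so any difference between the genotypes in which genes mark the ends lowers it. The ratio therefore does not show that regional differences are weaker in KO.

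At E14.5 the comparison asked what had changed in the embryonic cortex. No gene passed correction, in limma at an adjusted p under 0.05 (smallest adjusted p 0.85), and 1048 of 18194 genes had an unadjusted p under 0.05, against 909.7 by chance. Layer 6 genes lay lower as a set in KO (median log2 difference -0.15, 0 of 11 called, 2 fell adjusted over the list alone; camera adjusted p = 0.00302, and adjusted p = 0.466 with an estimated correlation), with Sox5 at -1.24 (SE 0.349) and Hs3st4 at -0.79. Axon guidance genes (Epha5 -2.38, Epha3 -1.96, Sema5a -1.30, but Efna5 1.12) and cadherins and protocadherins (Pcdh9 -0.74) also lay lower as sets, each with a camera adjusted p of 0.00116 and adjusted p = 0.291 with an estimated correlation. Without KO replicate 1 the cadherin list did not pass (camera adjusted p = 0.0826), and radial glia genes (0.0293) passed as higher and GABAergic interneuron (0.0482) and glutamate receptor genes (0.0393) as lower. The values without KO replicate 1 are with the preset correlation alone. Reln stood at -1.18 (SE 0.31), Bcl11b at -1.08, Ccn2 at 1.47 and Crym at 1.53, with limma adjusted p of 0.85 each. These values are of each gene's probe set with the highest mean. Over all its probe sets Epha5 ranged from -2.38 to -0.151, Epha3 from -1.96 to 0.141, Sema5a from -1.30 to -0.0107 and Efna5 from 0.108 to 1.12. Reln ranged from -1.18 to -0.0691, Sox5 from -1.57 to -0.139 and Pcdh9 from -0.737 to -0.0277, while Bcl11b ranged from -1.19 to -0.81.

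Marker lists of meninges and choroid plexus, tissues around the neocortex, lay higher as sets with the preset correlation in the same KO arrays, though not with an estimated correlation. Meninges and fibroblast genes had a median difference of 0.92 (4 of 7 rose and none fell adjusted over the list alone; camera adjusted p = 5.07e-05), with the collagen genes Col1a1 at 2.77, Col1a2 at 2.25 and Col3a1 at 1.53. Choroid plexus genes had a median of 0.79 (adjusted p = 0.0198), with the water channel Aqp1 at 2.11, and microglia genes one of 0.42 (adjusted p = 0.00302). With an estimated correlation these 3 lists had adjusted p of 0.43, 0.43 and 0.489. Thalamus genes had a median of 0.67 (adjusted p = 0.351), with Lhx9 at 1.23 and Gbx2 at 1.42. Over their probe sets Col1a1 ranged from 0.841 to 2.77, Col1a2 from 0.0773 to 2.86, Col3a1 from 1.53 to 1.89 and Lhx9 from 0.00434 to 1.23.

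The E14.5 arrays correlated best by replicate number, so the fit was also run with the number as a block. It called 0 genes, with 1401 at an unadjusted p under 0.05, and Tbr1 had an adjusted p of 0.568. In that fit the layer 6 (2.20e-04), axon guidance (0.00217), cadherin (5.02e-04), choroid plexus (0.00562), meninges (1.77e-04) and microglia lists (0.00227) passed the camera test, as did GABAergic interneuron (0.00704) and glutamate receptor genes (0.0252), both lower in KO, and with an estimated correlation no adjusted p was under 0.457. Without KO replicate 1, and with array weights, 2 genes were called, the Cajal-Retzius factor Ebf3 (2.49 and 2.34) and Zic4 (2.09 and 2.11), and without KO replicate 3, 30 genes were called, led by Col1a1 (3.83). These genes lie outside the rule that chose the named genes and were chosen after their values were seen.

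The effects at E14.5 and P0.5 were set side by side over 16553 genes measured on both arrays. As no gene was called at E14.5, none was called at both stages. Of 1412 genes called over the P0.5 regions, 802 (56.8%) had the same sign at E14.5, against 48.8% of all genes, and 51.9% without E14.5 KO replicate 1. Of these genes 126 had an unadjusted p under 0.05 at E14.5 (84.1 by chance; Fisher's exact test, two-sided, odds ratio 1.63, p = 3.11e-06), 72 with the same and 54 with the opposite sign. The correlation of the changes across all genes was 0.024. Genes are not independent replicates, so neither this correlation nor the Fisher p measures a spread over animals. The Fisher test also leaves out the sign. Tbr1, Sox5, Hs3st4 and Reln were lower in KO at both stages, without a call at E14.5. Over their E14.5 probe sets Reln ranged from -1.18 to -0.0691 and Sox5 from -1.57 to -0.139. Among genes of opposite sign were Epha5 (-2.38 at E14.5 and 0.38 at P0.5), Ccn2 (1.47 and -0.35) and Bcl11b (-1.08 and 0.18). The E14.5 probe sets of Epha5 ranged from -2.38 to -0.151. Ccn2 was also among the 30 genes called at E14.5 without KO replicate 3, which were led by Col1a1. Whether the higher meninges and fibroblast markers of the E14.5 KO arrays account for its rise there was not tested.

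Genes beside Tbr1 on its chromosome were also followed in the P0.5 comparison over the regions. Of its 40 nearest measured genes, 20 on each side, 12 were called, which is 30%, against 13.3% of the next 60 genes and 10.5% of genes more than 400 places away. The neighbours on either side changed most, with the proteasome gene Psmd14 at -0.95 (limma adjusted p = 3.60e-07) and Slc4a10 at 1.13. The sodium channel genes Scn1a (0.45) and Scn9a (0.42) and the glucagon gene Gcg (0.52) rose too. Cwc22 and Neurod1, among the largest rises, lie on the same chromosome, 109 and 114 measured genes away, and of the 200 genes from 101 to 200 places away 16 were called, which is 8%. Psmd14, Scn1a, Scn9a and Gcg lie outside the rule for named genes and were chosen after their values were seen.

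**Figure D5:**
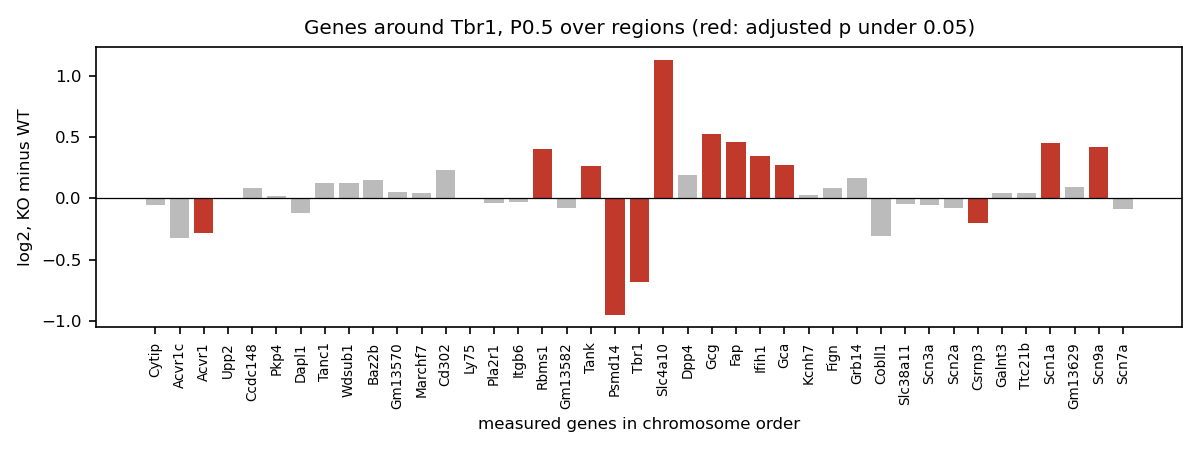
Log2 difference (KO minus WT, P0.5, mean of 3 regions, n = 4 and 4) of Tbr1 and its 20 nearest measured genes on each side, in chromosome order; red bars have a limma adjusted p under 0.05. Psmd14 (-0.95) and Slc4a10 (1.13), next to Tbr1, have the largest differences.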

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

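The test of WT frontal replicate 4 for the frontal calls was chosen after its result had been seen, and the fits with the Y-linked level as a covariate and the list values without E14.5 KO replicate 1 are tests chosen after the data had been seen.

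Genes called in frontal tissue stood beside a Y-linked gene level of 5.39 in KO and 9.04 in WT arrays, so the animals' sex could have added to the calls. Over the 1495 called genes other than the sex-linked ones, the slope on the Y-linked level within parietal and occipital groups (16 arrays) predicted a mean difference of 0.0523 (SE 0.0201), against a mean size of 0.46 and a bound of 0.23. If that slope holds in frontal tissue, this argues against sex as the cause of the calls as a set. The frontal arrays cannot show whether it holds, since their Y-linked levels part with genotype. Some of the 16 arrays had intermediate Xist, and what the Y-linked level means in them stays open. With the covariate 1494 of the 1495 genes kept their sign and the median size went from 0.39 to 0.35, while the median SE went from 0.0945 to 0.128 and 245 stayed called, so the wider error ended most calls. WT frontal replicate 4, the array least correlated with the others, lowered the sizes most when left out. Without it the called genes kept a median of 88.3% of their size (5th percentile 69.1%), against 95.8% to 108% without each other frontal array. Of the calls 53.2% stayed, as against 49.8% without KO frontal replicate 4. The genes were called with this array included, and leaving out any 1 array brought none under 0.5 of its size, so this cannot decide the array's part. The loss of Tbr1 is the explanation the design names, as a hypothesis, and a part from sex stays open.

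Genes next to Tbr1 on its chromosome differed between KO and WT at P0.5 over the regions. Of 38 neighbours tested (Psmd14 and Slc4a10, seen before the test, were left out), 10 were called, 8 higher and 2 lower, against a median of 2 and a 95th percentile of 7 over 18444 windows of the same size. The 10 calls fit a genome segment carried with the targeted allele, which may explain them, as a hypothesis. A local effect of the altered locus, or regulation of these genes by Tbr1, stays open and was not tested. The same explanations stay open for Slc4a10 and Psmd14, and were not tested for Cwc22 and Neurod1, 109 and 114 measured genes away on the same chromosome.

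Lists of meninges and fibroblast, choroid plexus and thalamus markers had medians of 0.92, 0.79 and 0.67 in E14.5 KO minus WT, with camera adjusted p of 5.07e-05, 0.0198 and 0.351, and adjusted p = 0.43, 0.43 and 0.67 with an estimated correlation. None of these genes stands in another list, but 5 of 7, 2 of 7 and 4 of 6 also lay above the median of all genes (6.02) in the WT arrays, and the collagen genes were at 11.4, 11.1 and 8.09 (Col1a1), 11.4, 11.6 and 9.32 (Col1a2) and 11.7, 12.4 and 10.7 (Col3a1) in the KO arrays, with Col3a1 at 10.1 in WT. Second lists of other markers, written after this was seen but before their own values were, had medians of 1.07 (6 of 6 higher), 0.231 (5 of 5) and 0.524 (7 of 7), each above the 95th percentile of random gene sets (0.181, 0.182 and 0.166, without the correlation between genes of 1 tissue), with 4 of 6, 1 of 5 and 1 of 7 above the median of all genes in WT. These values fit meninges and fibroblasts, choroid plexus and thalamus in the KO samples, as a hypothesis, and a change of these tissues in the embryos themselves stays open and was not tested. The collagen genes were higher in KO replicates 1 and 2 than in KO replicate 3, and the Col1a1 difference was 2.77 with all arrays and 3.83 without KO replicate 3. The list medians were not taken without KO replicate 2 or 3. KO replicate 1, the array least correlated with the others, was not the cause by itself, since without it the medians of the first lists were 1.11, 0.44 and 0.87, and 3 of the 3 stayed above 0.5 of their size, while those of the second lists were 0.777, 0.211 and 0.244, the last (thalamus) under 0.5 of its size, so this array carried much of that value.

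Other splits of the same arrays into groups of equal size were fitted in the same way. For each of the 7 P0.5 comparisons 1 of 35 splits, the real one, gave as many calls. With 35 splits no smaller share was possible, and 7 comparisons were read, so this alone does not exclude chance. In frontal tissue the real split also parted the Y-linked levels, so its count is not tied to genotype alone. The real count and the highest of the others were 1499 and 972 in frontal, 361 and 279 in parietal and 267 and 13 in occipital tissue, and 1488 and 0 over the regions. They were 1202 and 718 for WT frontal against occipital tissue, 643 and 0 for KO, and 83 and 0 for the interaction. The 972 came with KO frontal replicate 2 and WT frontal replicate 1 exchanged, the 279 with KO parietal replicate 2 and WT parietal replicate 1 exchanged, and the 718 with frontal and occipital replicates 1 and 4 of WT on 1 side. This last split follows replicate number and not region, so differences tied to the number in these WT arrays stay open. At E14.5 the 10 splits are too few for such a test (10 of 10 gave at least the real count of 0, and the highest other was 1), and among the 4 splits that part every numbered pair the highest other was 0.

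The interaction test called 83 genes for a frontal to occipital difference that depended on genotype, among them Il1rapl2 (1.70), Ndnf (1.69), Cntn6 (1.66), Klhl4 (1.61), Egfem1 (1.52), Kitl (-1.49), Bhlhe40 (-1.39), Bcl6 (-1.36), Zfp385b (-1.09) and Pappa2 (-1.05). The count was 12 with the Y-linked level as a covariate and 29 to 187 with 1 array left out. Of the genes named here, Cntn6, Egfem1 and Bhlhe40 stayed called with the covariate. Kitl and Klhl4 lost their calls in most cases of 1 array left out.

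Of 336 tests of a single array far from the other 3 of its group, 20 passed, against 16.8 by chance. The Y-linked genes stood apart in KO occipital replicate 3, with Eif2s3y at 6.17 (others 10.02 to 10.2), Kdm5d at 5.88 (8.37 to 8.59) and Uty at 5.60 (8.67 to 9.17). They did so in WT parietal replicate 2, with Eif2s3y at 6.12 (10.03 to 10.21), Kdm5d at 5.79 (8.39 to 8.56) and Uty at 5.37 (8.68 to 9.02). In KO frontal replicate 4 Eif2s3y was at 6.14 (4.58 to 4.84). In WT frontal replicate 3 Cwc22 was at 11.3 (9.05 to 9.40), Egfem1 at 6.57 (7.06 to 7.14), Pla2g7 at 6.74 (7.56 to 7.71) and Usp17ld at 9.38 (8.46 to 8.56). In WT frontal replicate 4 Il1rapl2 was at 5.49 (6.15 to 6.23) and Nefl at 8.72 (8.997 to 9.048). In WT frontal replicate 1 S100a10 was at 11.0 (11.1 to 11.1). In WT occipital tissue Arhgap29 was at 9.21 in replicate 3 (8.98 to 8.998), Ptprn at 8.31 in replicate 1 (8.22 to 8.23) and Trps1 at 9.47 in replicate 4 (7.80 to 8.05). In KO parietal replicate 1 Usp17ld was at 9.70 (7.51 to 7.84), in WT parietal replicate 3 Il1rapl2 at 6.30 (6.71 to 6.75), and in WT parietal replicate 1 Npy at 11.1 (11.3 to 11.3).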

How the results depend on the processing

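The tests chosen after the data had been seen are the fits with the Y-linked level as a covariate and those without WT frontal replicate 4 and KO parietal replicate 2. The others are, for neighbouring regions alone, the fits of only 8 arrays or with a block, and the E14.5 list values without KO replicate 1. For the genes named by the rule, 16121 of 16948 values under an alternative kept their side of the threshold, 602 lost a call, 222 gained one and 3 reversed. For the lists it was 551, 66, 7 and 0 of 624. Genes and lists that passed in neither fit count as kept whatever their sign, so these totals do not measure how many calls held. The 3 that reversed were Uty (0.171) and Kdm5d (0.279) in frontal tissue and Uty over the regions (0.0787), all with the Y-linked level as a covariate, which is made from these genes. A 1.5-fold minimum, which removes calls by construction, left 284 genes in frontal, 122 in parietal and 89 in occipital tissue, 129 over the regions, 209 between the ends of the axis in WT and 199 in KO. With array weights the counts were 2 at E14.5, 2606 frontal, 1241 parietal, 664 occipital, 1549 for KO frontal against occipital tissue and 530 for the interaction, and the cause was not tested. Fits of only the 8 arrays compared gave fewer calls in frontal tissue (687), occipital tissue (224) and for WT frontal against occipital tissue (287). They gave more in parietal tissue (415) and for KO frontal against occipital tissue (722), and the cause was not tested. With the Y-linked level as a covariate the counts were 247 frontal, 824 over the regions (1891 in the same fit of 24 arrays without it), 247 for KO frontal against occipital tissue and 12 for the interaction. Without WT frontal replicate 4 and KO parietal replicate 2 they were 419 occipital, 782 for WT, 1025 for KO and 46 for the interaction, and the cause was not tested. Leaving out 1 array at a time (over the regions, the 3 arrays of a genotype and number) gave 0 to 30 at E14.5, 749 to 2454 frontal, 237 to 357 parietal, 122 to 358 occipital, 963 to 1494 over the regions, 441 to 1917 for WT, 441 to 540 for KO and 29 to 187 for the interaction. With the replicate number as a block they were 1438, 376, 278, 1298, 1076, 658 and 79 in the P0.5 comparisons, in the same order, and for neighbouring regions they went from 34 to 47 (frontal and parietal) and from 90 to 104 (parietal and occipital) in WT, and from 47 to 72 and from 70 to 101 in KO. Outside the neighbouring regions, the other alternatives kept each count within 1.5 times. The ratio of regional differences in KO to WT was 0.615 with 50 and 0.602 with 200 genes each way. Subtracting array medians moved the median of all genes by at most 0.047. What lies near the background on the arrays limits the dimmest genes.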

Other observations

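The tests here were chosen after the values were seen.

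Members of 2 gene families moved unequally at P0.5 over the regions. Of the neurofilament genes, Nefl (1.31) and Nefm (1.36) rose, while Nefh stood at -0.075 (limma adjusted p = 0.462) and the related intermediate filament gene Ina at 0.10 (adjusted p = 0.319). With array medians subtracted the values were 1.32, 1.37, -0.071 and 0.11. Of the nuclear factor I genes, transcription factors of neural development, Nfia (-0.92), Nfib (-0.32) and Nfix (-0.26) fell, and Nfic stood at -0.012 (adjusted p = 0.925). With array medians subtracted they stood at -0.92, -0.32, -0.26 and -0.0087.

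Xist was intermediate in 5 P0.5 arrays whose Y-linked genes were high, at 7.75 and 8.77 in KO occipital replicates 2 and 4, at 8.54 and 7.88 in KO parietal replicates 1 and 3, and at 8.65 in WT parietal replicate 3, with Y-linked means of 9.02 to 9.19. Cwc22, whose gene is read by 8 probe sets on the P0.5 array, spread from 9.05 to 11.3 over the WT frontal arrays.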
